A study of Arabidopsis thaliana and Arabidopsis suecica and Arabidopsis arenosa x Arabidopsis thaliana with 58 samples.

How the data were processed

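The study has 58 samples. The 48 array samples were used, and the 10 sequencing libraries, among them the first-generation hybrids, were not analysed here because no processed values were present for them. Each array had 351 probes with 1 spot each, 161 for Arabidopsis small RNAs and 190 for microRNAs of other organisms. Per the labels, RNA was enriched for small molecules and labelled with a single dye, Cy5. Scanner settings and the wash protocol were not given in the sources used here. The samples were 9 leaf arrays and 3 flower bud arrays for each of 4 species.

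The values were the foreground median intensity of each spot, a raw fluorescence intensity per the file headers. The authors' deposited value table holds the log2 of the same intensity. No background column and no negative controls were present.

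Per the file headers, array files with consecutive numbers share a sector number, so the 3 arrays of a set were taken as replicate spots of 1 hybridization. This gave 3 leaf sets and 1 flower set per species, and each leaf set held all 4 species. The sample labels give 12 intensities in 3 biological replicates per species and do not say which arrays those are, so the 3 bud arrays of a species could instead be separate samples. The median intensity of an array differed several-fold between sets.

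The deposited array files and the deposited value table were matched value by value. Of the 48 arrays, 36 equalled the column of their own sample and 12 equalled the column of another. Those 12 were leaf arrays 4 to 6 of every species. In the value table the A. arenosa columns hold the values of the A. thaliana files, the F7 columns those of A. arenosa, the A. suecica columns those of F7, and the A. thaliana columns those of A. suecica. Which source is right was not given in the sources used here. The files' labels had been fixed before the data were examined and were kept for the results that come first. The value table had been listed as an alternative at that time, and its results were selected for a place beside the others after values were seen. Leaving out the 12 arrays was chosen after seeing the data.

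Intensities were background-corrected by the normexp method with an offset of 50, transformed to log2 and quantile normalized over the 48 arrays. A probe was tested if it was an Arabidopsis probe above the array median on at least a share of 0.5 of the arrays of at least 1 of the 8 groups. This left 97 probes and set aside 64. The same rule left 94 with the value table.

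Each probe was fitted with limma (lmFit and eBayes) with 1 mean for each of the 8 groups. Sets were a random block through duplicateCorrelation. The consensus correlation within sets was 0.603, with 40 residual and 8.01 prior degrees of freedom. It was 0.523 with the value table and 0.481 without leaf arrays 4 to 6. Contrasts of group means gave the comparisons, and the progenitor mean is the average of the 2 log2 means. P-values were adjusted by Benjamini-Hochberg over the probes of each contrast, and a probe was called at an adjusted p under 0.05. The standard errors are those of the moderated fit. The p-values rest only on the spread between arrays, with 1 consensus correlation for the arrays of a set. Each species had 1 flower set, so the spread between sets in comparisons with flower was taken from leaf. The median standard deviation between leaf set means was 0.272, against 0.170 between spots within a set.

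The 11 lists of small RNAs were fixed before the data were examined. Those with at least 3 tested probes, 10 lists, were tested with camera with a preset correlation of 0.01, with Benjamini-Hochberg over lists in each contrast. Camera with an estimated correlation and fry were run beside it. Probes were named by a fixed rule, up to 6 in each direction by adjusted p in each contrast and up to 2 called members of each list. Where nothing passed, the probes with the lowest p-values are given.

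Whether equal array numbers pair samples across species was checked by correlating residuals from the group means. In flower all 18 pairs of arrays with equal numbers correlated above 0.1 (0.496 to 0.801), so results with the array number as a fixed block stand beside the flower results. In leaf the correlations were mixed, and only 16 of 36 arrays correlated best with their own number.

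Other organisms' probes served as a reference for background. It used 63 such probes, from 46 families whose number no Arabidopsis probe or listed ancient family shared, and the 95th percentile of these on each array. Likeness in sequence to Arabidopsis probes of another family number was not checked. The reference was chosen after seeing the data. The moss probes miR535a and miR535d and the rice probe miR528 are among the 63 and lay above it on 47, 47 and 33 of the 48 arrays, which sets the reference high. The arrays above it without these 3 probes are given where a statement of 0 arrays changed. Where a probe exceeded the reference on no array of 1 of 2 groups, its fitted difference is not exact. A bound was then taken from the other group's mean log2 level and, on each array of the dim group, the higher of the probe's own level and the lowest level of any probe above the reference. No fold is given where this bound lies under 1. The number of called probes was also counted for groupings of the leaf hybridizations of a comparison, all 10 ways for 2 species and 100 ways, the real one and random others, for an allotetraploid against the progenitor mean. With the set as a fixed block the species were also exchanged within each leaf set only, in all 4 ways for 2 species and 100 of the ways for 3.

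A simulation with known changes put into the 97 probes gave the share recovered. For A. arenosa against A. thaliana in leaf 76.5% of changes of 2-fold and 98.5% of changes of 4-fold were found. In flower the shares were 41% and 85.5%, and for flower against leaf in A. arenosa 57.5% and 95%. False calls averaged 1, 0.65 and 1 per simulation. The simulated values followed the fitted model, with 1 correlation for all probes and correct species labels. They had no set effect shared by the species and no lower limit of intensity. The shares therefore do not tell how often a change is found under wrong labels or near background.

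The tested probes carry the names of A. thaliana small RNAs, so a difference in sequence in A. arenosa would lower a signal. Binding of 1 family member's RNA to another's probe was not tested. The software was R 4.3.3 with limma 3.58.1 and statmod 1.5.0.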

Results

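Small RNA levels were compared between Arabidopsis thaliana (a tetraploid line), A. arenosa, the F7 progeny of a synthetic allotetraploid made from these 2 species, and the natural allotetraploid A. suecica. Each species was measured in leaves and in flower buds on oligonucleotide arrays, on which 97 probes for Arabidopsis small RNAs were bright enough to be tested. In leaf, the deposited array files and the deposited value table give different species for arrays 4 to 6. The array files' labels were used, and each leaf comparison of single small RNAs is also given with the value table's labels and without those arrays. Mean correlation with the same species' other leaf sets was 0.518 with the value table's labels, the highest of 24 ways, and -0.250 with the files'. The order of the species by position in the files went with the files' labels. If those labels are wrong, the files' leaf and flower to leaf results mix species.

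With the array files' labels, no small RNA differed between A. arenosa and A. thaliana leaves at an adjusted p under 0.05. The lowest p-values belonged to 2 trans-acting siRNA probes of almost the same sequence and to miR169a, which acts on NF-YA transcription factors. The probe ta-siR255 was 0.81 lower in log2 in A. arenosa (standard error 0.24, adjusted p = 0.129), ta-siR461 was 0.75 lower (0.25, adjusted p = 0.186) and miR169a was 0.75 lower (0.27, adjusted p = 0.186). In A. arenosa neither ta-siR255 nor ta-siR461 exceeded the 95th percentile of other organisms' probes on any of 9 arrays, so these 2 fitted sizes are not exact. Without the miR535 and miR528 probes in that reference ta-siR255 exceeded it on 2 of 9 and ta-siR461 on 0. The miR163 probe, for a young microRNA of the Arabidopsis lineage that acts on methyltransferase genes, was 1.21 lower (standard error 0.62, adjusted p = 0.542). Its difference was -3.48 in the first hybridization set, 3.17 in the second (arrays 4 to 6) and -3.32 in the third. By limma with Benjamini-Hochberg adjustment 0 of 97 probes passed, and 6 had an unadjusted p under 0.05, with 9 arrays from 3 hybridizations per species. With the hybridization set as a fixed block as well, chosen after seeing the data, 4 passed: ta-siR255 (adjusted p = 0.00775), and ta-siR461, miR169a and AtsRR166927 (each adjusted p = 0.0223).

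With the value table's labels, an alternative listed before the data were examined and selected after values were seen, miR163 was the largest difference between the leaves of the 2 progenitors. It fell by 3.59 in A. arenosa (standard error 0.33, adjusted p = 1.79e-12), with -3.48, -3.99 and -3.32 in the 3 sets. The trans-acting siRNA probes ta-siR461 (-1.11), ta-siR752 (-0.80) and ta-siR255 (-0.76) also fell in A. arenosa, as did 3 of the miR169 family, miR169a (-0.98), miR169d (-0.92) and miR169b (-0.82), and the uncharacterised small RNA smRNA57 (-1.50). In A. arenosa miR163, ta-siR461, ta-siR752 and smRNA57 exceeded the 95th percentile of other organisms' probes on 0 of 9 arrays, against 9, 7, 5 and 6 of 9 in A. thaliana, so their fitted sizes are not exact. Measured from the lowest signal above that level, A. thaliana had at least 4.67-fold more miR163 and at least 1.16-fold more ta-siR461, and no fold can be given for ta-siR752 and smRNA57. Higher in A. arenosa were AtsRR166927 (1.58), a small RNA without an assigned function, and miR160a (0.97), which acts on auxin response factors. These 10 probes, 2 higher and 8 lower, passed limma with Benjamini-Hochberg adjustment over 94 probes, and 28 passed with the fixed block added. Without arrays 4 to 6, a choice made after seeing the data, 8 of the 10 passed, with miR163 at -3.63 (standard error 0.41, adjusted p = 1.73e-08). Among the 10 ways to group these leaf hybridizations only the real one gave as many, and the highest count in any other was 8.

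**Figure D1:**
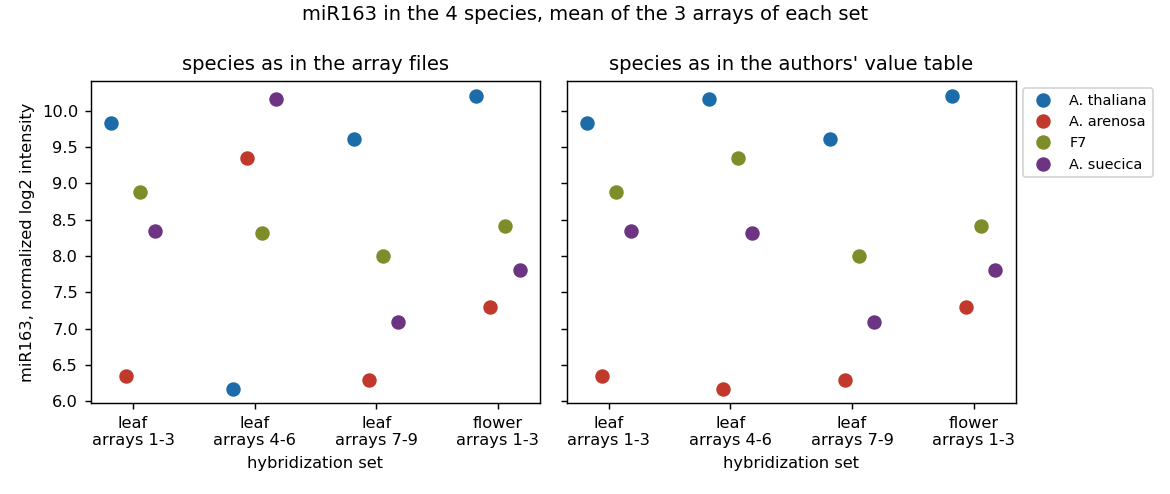
Level of miR163 in each hybridization set of the 4 species, with the species of leaf arrays 4 to 6 taken from the array files and from the value table. Each point is the mean of the 3 arrays of 1 hybridization.

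In leaf, miR163 in A. suecica differed from both progenitors when the value table's labels were used, and so did F7. F7 was 1.12 lower than A. thaliana (standard error 0.33, adjusted p = 0.0276) and 2.47 higher than A. arenosa (adjusted p = 1.57e-07). A. suecica was 1.94 lower than A. thaliana (adjusted p = 4.20e-05) and 1.65 higher than A. arenosa (adjusted p = 4.34e-04). Without arrays 4 to 6, F7 passed against A. arenosa (2.34, adjusted p = 9.74e-05) and not against A. thaliana (-1.29, adjusted p = 0.0724), and A. suecica passed against both (1.58, adjusted p = 0.0113, and -2.05, adjusted p = 8.70e-04). Mean log2 levels over 3 hybridizations were 9.87 in A. thaliana (standard deviation 0.28), 6.27 in A. arenosa (0.09), 8.74 in F7 (0.68) and 7.92 in A. suecica (0.72). With the array files' labels the leaf means were 8.54 (2.05), 7.33 (1.75), 8.40 (0.45) and 8.54 (1.54), and no miR163 difference passed. The test was limma with Benjamini-Hochberg adjustment. With the value table's labels miR163 in A. arenosa leaves lay below the 95th percentile of other organisms' probes on all arrays of the 3 sets (for example 51 against 74.5 intensity units), so the fitted differences from A. arenosa are not exact. Measured from the lowest signal above that level, F7 had at least 2.14-fold and A. suecica at least 1.21-fold more than A. arenosa, with 9 and 6 of 9 arrays above it. In set 3 A. suecica was near that level too (58 against 61.65), with 1 of 3 arrays above it. In that set A. arenosa and A. suecica had each other's usual position in the files, and an exchange of these 2 was not tested.

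Against A. arenosa alone, A. suecica leaves had higher signal at 3 of the 10 trans-acting siRNA probes tested, which have almost the same sequence and match siRNAs of the miR173-cleaved TAS1 transcripts. With the array files' labels ta-siR752 rose by 0.999 (standard error 0.23, adjusted p = 0.00884), ta-siR461 by 0.92 (0.25, adjusted p = 0.0332) and ta-siR255 by 0.81 (0.24, adjusted p = 0.0461). No other probe passed in F7 or A. suecica against either progenitor, in leaf or in flower. With the array number as a fixed block in place of the sets, leaf and flower together, more passed, but that fit counts the arrays of a set as separate samples. Under the value table's labels ta-siR752 (1.18) and ta-siR461 (0.98) passed again, and without arrays 4 to 6 ta-siR752 (1.36), ta-siR461 (1.09) and ta-siR255 (0.91) did. Over the 8 comparisons with single progenitors there were 29 calls with the value table's labels, 3 with the files' and 26 without arrays 4 to 6, some probes being called in several. The calls are from limma with Benjamini-Hochberg adjustment, and in A. arenosa leaves ta-siR255, ta-siR461 and ta-siR752 exceeded the 95th percentile of other organisms' probes on 0 of 9 arrays, against 8, 7 and 5 of 9 in A. suecica, so the fitted sizes are not exact. Measured from the lowest signal above that level, ta-siR255 was at least 1.04-fold higher in A. suecica with the files' labels, and no fold can be given for ta-siR461 and ta-siR752. With the miR535 and miR528 probes left out of the reference ta-siR255 exceeded it on 2 of 9 A. arenosa arrays, so that bound depends on the reference.

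In F7 leaves no small RNA departed from the mean of the 2 progenitors with the array files' labels. The 2 highest probes were miR172e (0.69, standard error 0.25) and miR172a (0.67, standard error 0.25), which act on the AP2-type repressors of flowering, both with an adjusted p = 0.443. Both rose with the value table's labels, miR172e by 0.86 and miR172a by 0.79, together with smRNA57 (0.67), each with an adjusted p = 0.0136. The smRNA57 probe exceeded the 95th percentile of other organisms' probes on 0 of 9 A. arenosa arrays and 2 of 9 F7 arrays there, so its size is not exact. The 2 miR172 probes passed without arrays 4 to 6 as well, at 0.96 and 0.93 (adjusted p = 0.00527). In limma with Benjamini-Hochberg adjustment 0 of 97 probes passed with the files' labels and 5 had an unadjusted p under 0.05. The count was 3 with the value table's labels and 9 with the fixed set block added to them. As many as 3 passed in 25 of 100 groupings of the leaf hybridizations, the real one included.

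In A. suecica leaves ta-siR752 was 0.75 above the mean of the progenitors with the array files' labels (standard error 0.20), just short of the threshold (adjusted p = 0.0555). No other probe came near, and miR172e was 0.57 higher (standard error 0.25, adjusted p = 0.889). Taken by the value table's labels, miR172e rose by 0.95 and ta-siR752 by 0.78 (both adjusted p = 0.00157), miR172a by 0.78 (adjusted p = 0.0154) and miR160a by 0.60 (adjusted p = 0.0388), while miR158b, a Brassicaceae microRNA, fell by 0.59 (adjusted p = 0.0438). Without arrays 4 to 6, miR172e, miR172a, ta-siR752 and miR158b passed in the same directions. By limma with Benjamini-Hochberg adjustment 0 of 97 probes passed with the files' labels and 4 had an unadjusted p under 0.05, and with the fixed set block added ta-siR752 passed (adjusted p = 0.00545). The value table's labels gave 5, and 13 with the fixed set block added. As many as 5 passed in 23 of 100 such groupings. In A. arenosa leaves ta-siR752 was not above the 95th percentile of other organisms' probes on any array under either set of labels, so its size is not exact.

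Between the 2 allotetraploids, leaf small RNA levels did not differ at any probe with the array files' labels. The lowest p-value belonged to miR158b, which was 0.43 lower in A. suecica than in F7 (standard error 0.24), and ta-siR752 was 0.30 higher (0.23). By the value table's labels ta-siR752 rose by 0.76 in A. suecica (standard error 0.19, adjusted p = 0.0197), and without arrays 4 to 6 the 1 probe that passed was miR158b, at -0.93 (0.24, adjusted p = 0.0491). In limma with Benjamini-Hochberg adjustment 0 of 97 probes passed with the files' labels, and 0 had an unadjusted p under 0.05. The value table's labels gave 1, and as many passed in 3 of 10 such groupings. With the fixed set block added to the value table's labels 12 passed, among them miR163 (-0.82, adjusted p = 0.0113), which was -0.53, -1.02 and -0.90 in the 3 sets.

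Among the fixed lists in leaf, the trans-acting siRNAs stood above the progenitor mean in A. suecica with the array files' labels. Of their 10 tested probes 8 were higher, with a mean of 0.18, but 0 rose and 0 fell by the single-probe test, and ta-siR752 alone passed when adjusted over the list alone. The list passed camera with the preset correlation (adjusted p = 0.0357) and did not pass with an estimated one (adjusted p = 0.413 with an estimated correlation). Nor did it pass under median scaling (7 of 10 higher, adjusted p = 0.636), 75th percentile scaling (5 of 10, adjusted p = 0.630) or no normalization (6 of 10, adjusted p = 0.622). In F7 the same 10 probes did not pass (mean 0.13, adjusted p = 0.0851), nor did they in A. arenosa against A. thaliana (mean -0.25, adjusted p = 0.0842), where 2 passed when adjusted over the list alone. The 9 phase change probes (miR156, miR157 and miR172) and the 14 nutrient and metal stress probes (miR169, miR395, miR397, miR398, miR399 and miR408) had no member that rose or fell in any of the 4 leaf comparisons with the files' labels. With the value table's labels 2 phase change probes, miR172a and miR172e, rose in F7 and in A. suecica, and 3 nutrient probes, miR169a, miR169b and miR169d, fell in A. arenosa. Without arrays 4 to 6 the same 2 rose, and of the 3 only miR169a fell. For the trans-acting siRNAs in A. suecica against the progenitor mean, camera gave an adjusted p = 0.0533 with the value table's labels and an adjusted p = 0.229 without arrays 4 to 6. The list did pass in A. suecica against F7 with the value table's labels (mean 0.29, adjusted p = 0.00669, and adjusted p = 0.0927 with an estimated correlation). Camera's p-values were adjusted by Benjamini-Hochberg over the 10 lists of each comparison.

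In flower buds the largest difference between the progenitors was again at miR163, with a log2 difference of -2.91 for A. arenosa minus A. thaliana (standard error 1.07), which did not pass with the array files' labels (adjusted p = 0.375). Also among the lowest p-values were miR164c, which acts on CUC genes at organ boundaries, 1.24 lower (0.39, adjusted p = 0.250), and miR447a, a lineage-restricted microRNA (adjusted p = 0.375). The miR447a probe exceeded the 95th percentile of other organisms' probes on 3 of 3 A. thaliana and 0 of 3 A. arenosa arrays. Measured from the lowest signal above that level, A. thaliana had at least 1.36-fold more. The flower arrays themselves carry the same labels in both sources, but the spread of the leaf arrays enters their error. Under the value table's leaf labels miR163 fell by 2.91 (standard error 0.58, adjusted p = 6.39e-04), and its difference was -2.41 for A. suecica minus A. thaliana (adjusted p = 0.0119). Without leaf arrays 4 to 6 miR163 passed at -3.01 (standard error 0.59, adjusted p = 9.35e-04). In flower its signal exceeded the 95th percentile of other organisms' probes on all 3 A. arenosa arrays (206 against 124.3 intensity units). In limma with Benjamini-Hochberg adjustment 0 of 97 probes passed with the files' labels and 5 had an unadjusted p under 0.05. There the 3 arrays per species were taken as 1 hybridization. With the array number as a fixed block in place of the sets 8 passed, and with each flower array as its own set 7 passed. Both of these fits count the 3 arrays of a species as separate samples.

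Flower buds of the allotetraploids showed no single probe away from the progenitor mean with the array files' labels, and the lowest values were in the miR169 family. In A. suecica miR169a was 1.36 below that mean (standard error 0.40, adjusted p = 0.127), miR169d 1.26 below (0.47, adjusted p = 0.324) and miR169b 1.25 below (0.43, adjusted p = 0.281). In F7 miR169b was 0.91 below (0.43) and miR169a 0.77 below (0.40), both with an adjusted p = 0.999. The trigger of TAS1 processing, miR173, was 1.04 higher in A. suecica than in F7 (0.45, adjusted p = 0.999). A. suecica miR169a fell by 1.36 with the value table's leaf labels (standard error 0.33, adjusted p = 0.0154), and it was the only probe to pass there without leaf arrays 4 to 6 too. In limma with Benjamini-Hochberg adjustment 0 of 97 probes passed with the files' labels in F7, in A. suecica and between them. Those with an unadjusted p under 0.05 numbered 1, 6 and 1, and with the array number as a fixed block 0, 11 and 1 passed. With each flower array as its own set 0, 6 and 1 did.

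Set against the other probes, the list of nutrient and metal stress microRNAs was lower relative to the progenitor mean in A. suecica flower buds, and in F7 buds with quantile normalization only. In A. suecica 10 of the 14 probes lay below the progenitor mean, with a mean of -0.44 (camera adjusted p = 2.38e-04, and adjusted p = 0.00162 with an estimated correlation). In F7 the mean was -0.22 (adjusted p = 0.0152, and adjusted p = 0.0485 with an estimated correlation). A. suecica passed under median scaling, 75th percentile scaling and no normalization too (adjusted p = 4.28e-04, 7.53e-04 and 6.71e-04, with 11, 7 and 12 probes below), and F7 passed under none of them (adjusted p = 0.0534, 0.0792 and 0.0541). Tested by fry against no change, the list did not pass in A. suecica (adjusted p = 0.0755) or F7 (adjusted p = 0.992). By the single-probe test 0 of the 14 rose and 0 fell in either, and in A. suecica 3 passed when adjusted over the list alone. The list includes miR169a, miR169b, miR169d and miR169h, whose sequences are alike, besides miR395, miR397, miR398, miR399 and miR408. In A. suecica miR169a, miR169b and miR169d, given above, lay well below the list mean. Whether the list passes without the miR169 probes was not tested, so the result may not hold for the other families. A. arenosa and A. thaliana buds did not differ over this list (mean 0.15, adjusted p = 0.339). Camera's p-values were adjusted by Benjamini-Hochberg over 10 lists, and the 3 bud arrays of a species were taken as 1 hybridization. The spread between hybridizations in these fits therefore came from the leaf sets.

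Flower buds had far more miR171a, which acts on the HAM group of GRAS transcription factors, than leaves in all 4 species. It rose by 1.15 in A. thaliana (standard error 0.37, adjusted p = 0.0438), 2.59 in A. arenosa (adjusted p = 6.36e-07), 2.19 in F7 (adjusted p = 2.80e-05) and 2.11 in A. suecica (adjusted p = 6.37e-05). The 2 miR157 probes, for microRNAs that act on SPL genes of the juvenile-to-adult transition, fell in 3 species with the array files' labels. For miR157a the values were -1.48 in A. thaliana, -1.59 in A. arenosa and -1.53 in A. suecica, and for miR157d -1.48, -1.37 and -1.25. Both fell in F7 as well with the value table's labels (-1.23 and -1.10, each adjusted p = 0.0326), and without leaf arrays 4 to 6 miR157a fell in all 4 species and miR157d in 2. Their relative miR156h fell in A. thaliana (-1.03) and A. arenosa (-0.95), as did ASRP1957, a cloned small RNA (-1.86 and -2.17). In A. thaliana the sign of miR156h turned under other scalings, to 0.095 with median scaling and 0.31 without normalization, neither of which passed. The calls are from limma with Benjamini-Hochberg adjustment, and the 3 bud arrays of a species were taken as 1 hybridization, in which case tissue and hybridization are not separable.

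**Figure D2:**
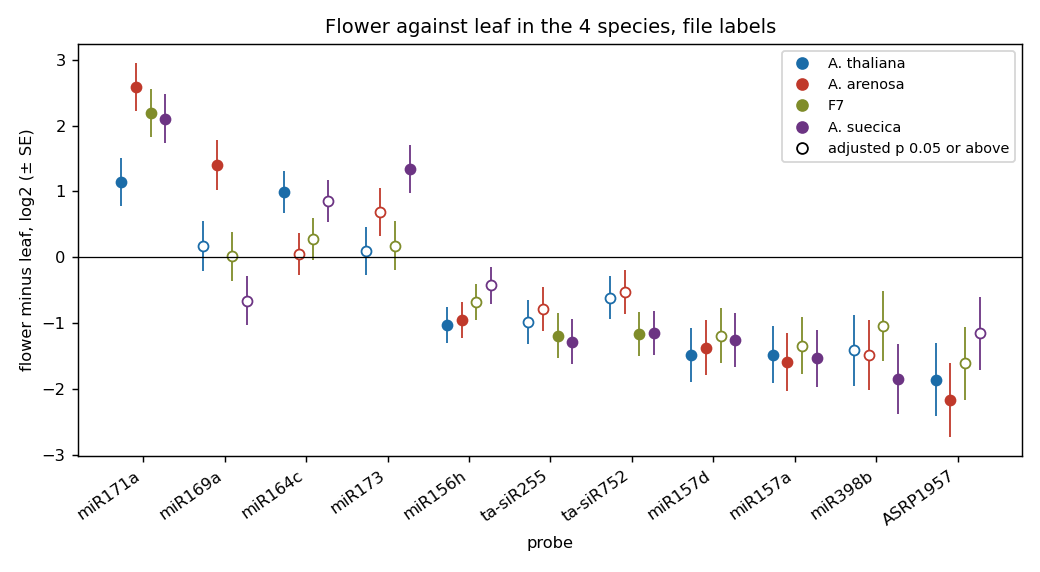
Flower minus leaf difference in log2 for probes that passed in at least 1 species, in each of the 4 species. Error bars are standard errors from limma.

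Other flower to leaf differences passed in fewer species with the array files' labels. In A. thaliana miR164c rose by 0.99 and ta-siR1745 fell (adjusted p = 0.0347). In A. arenosa miR169b (1.44) and miR169a (1.40) rose, as did smRNA49 (adjusted p = 0.00865). In F7 the trans-acting siRNAs ta-siR461, ta-siR255 and ta-siR752 fell (each adjusted p = 0.0285), and in A. suecica ta-siR255 and ta-siR752 fell along with miR398b, which acts on copper superoxide dismutase messages (each adjusted p = 0.0184). Higher in A. suecica buds were miR173 (1.34) and miR171* (adjusted p = 0.0330), the opposite strand of the miR171 duplex. The ta-siR255 probe passed in all 4 species with the value table's labels, and ta-siR752, ta-siR1745, ta-siR461 and ASRP1957 in 3. Without leaf arrays 4 to 6 ta-siR255, ta-siR752, ta-siR461, miR398b and miR158b passed in 3. The miR398b probe fell in A. thaliana too under those 2 choices (adjusted p = 0.00820 and 0.00683), with leaves at least 2.79-fold and 3.09-fold higher.

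Several of these probes were not above the 95th percentile of other organisms' probes on any array of 1 tissue, so only a bound can be given. The smRNA49 probe in A. arenosa exceeded it on 0 of 9 leaf and 3 of 3 bud arrays, and miR171* in A. suecica on 0 of 9 and 1 of 3, and no fold can be given for either. No bud array was above it for the probes that fell, and leaves had at least 1.20-fold more ta-siR1745 in A. thaliana (2 of 9 leaf arrays above). In F7 leaves the bounds were at least 1.64-fold for ta-siR461 (7 of 9), 1.51-fold for ta-siR255 (5 of 9) and 1.32-fold for ta-siR752 (3 of 9). In A. suecica leaves they were at least 1.45-fold for ta-siR255 (8 of 9), 1.34-fold for ta-siR752 (5 of 9) and 2.13-fold for miR398b (8 of 9).

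The number that passed was 7 of 97 in A. thaliana (2 higher, 5 lower), 8 in A. arenosa (4 higher, 4 lower), 4 in F7 (1 higher, 3 lower) and 8 in A. suecica (3 higher, 5 lower), by limma with Benjamini-Hochberg adjustment. With the value table's leaf labels these became 13, 16, 9 and 12, and without leaf arrays 4 to 6 they became 14, 19, 8 and 12. With each flower array as its own set, which counts the bud arrays as separate samples, they were 12, 24, 19 and 27. With set means as samples fewer passed in every species. Of the probes called with the files' labels 7, 8, 4 and 8 were called with the table's, and 6, 8, 4 and 7 without arrays 4 to 6. Leaving out 1 array number at a time gave from 0 to 8 in A. thaliana, 8 to 9 in A. arenosa, 1 to 4 in F7 and 5 to 9 in A. suecica, and in A. thaliana no probe passed without number 3 or without number 8. The counts fell to 0, 1, 0 and 0 when arrays were scaled by their median, and miR171a in A. arenosa was the one probe that still passed. The differences in miR171a were then 2.26, 3.84, 2.45 and 2.53, with a standard error of 0.81 in place of 0.37, so the call was lost in 3 species through the larger spread and not through smaller differences.

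No single probe passed for a tissue difference that varied between species with the array files' labels. The median standard error of these comparisons was 0.554, so differences of moderate size could be missed. For miR171a the rise in buds was larger in A. arenosa than in A. thaliana, 2.59 against 1.15, without passing as a difference. Under the value table's labels the flower to leaf change of miR172e in A. suecica minus that in A. thaliana was -1.85 (standard error 0.48, adjusted p = 0.0321), and without leaf arrays 4 to 6 it was -2.03 (0.44, adjusted p = 0.00543). In limma with Benjamini-Hochberg adjustment 0 of 97 probes passed with the files' labels for A. arenosa, F7 and A. suecica each against A. thaliana, and 5, 1 and 2 had an unadjusted p under 0.05.

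All 10 trans-acting siRNA probes tested had lower signal in buds than in leaves in each of the 4 species. In buds of A. arenosa, F7 and A. suecica none of them exceeded the 95th percentile of other organisms' probes on any array, and ta-siR1786 and ta-siR619 did so on none of the 48 arrays, so the sizes are not exact. Without the miR535 and miR528 probes in the reference, ta-siR461 in A. suecica, ta-siR619 in A. arenosa and ta-siR1511 in F7 exceeded it on 1 of 3 bud arrays, and ta-siR619 did on 1 A. thaliana, 3 A. arenosa and 1 A. suecica leaf arrays. In A. arenosa leaves only ta-siR289 and ta-siR1511 exceeded the full reference, each on 1 of 9 arrays, so the direction there mostly compares signals not above background. The direction of all 10 held under median scaling, 75th percentile scaling and no normalization. Most reference probes of other organisms also had a lower mean over bud than over leaf arrays. The shared direction alone therefore does not set these dim probes apart. Their mean was -0.56 in A. thaliana (1 fell, 9 did not pass), -0.47 in A. arenosa (0 fell), -0.72 in F7 (3 fell) and -0.64 in A. suecica (2 fell). The list passed camera in A. thaliana (adjusted p = 0.00482), F7 (adjusted p = 3.92e-04) and A. suecica (adjusted p = 0.0131), and not in A. arenosa (adjusted p = 0.188). With an estimated correlation only F7 kept it (adjusted p = 0.0499 with an estimated correlation), and A. thaliana (adjusted p = 0.118) and A. suecica (adjusted p = 0.0992) did not. Under the value table's labels 9 were tested, and the means were -0.64, -0.57, -0.61 and -0.76, with 4, 2, 3 and 4 that fell. All 4 species passed camera (adjusted p = 0.00673, 0.0489, 0.0112 and 0.00137), and only A. suecica did with an estimated correlation (adjusted p = 0.0440). Without leaf arrays 4 to 6 A. thaliana, F7 and A. suecica passed (adjusted p = 0.00254, 0.00168 and 0.00551), and none did with an estimated correlation. Among the 10, ta-siR255, ta-siR461 and ta-siR752 have almost the same sequence.

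The list of 9 phase change probes passed in buds of 2 species, A. arenosa and A. suecica, and under 3 other scalings it passed in neither. In A. arenosa all 9 were below leaf with a mean of -0.73, and miR157a, miR157d and miR156h fell (adjusted p = 0.0372, and adjusted p = 0.0270 with an estimated correlation). In A. suecica all 9 were below leaf with a mean of -0.69, and miR157a and miR157d fell (adjusted p = 0.0354, and adjusted p = 0.0534 with an estimated correlation). Under median scaling 5 of the 9 lay above leaf in A. arenosa (mean 0.0052, adjusted p = 0.514), with miR172a at 0.50 and miR156a at 0.34, and 2 did in A. suecica (mean -0.28, adjusted p = 0.374). Without normalization 5 and 4 lay above leaf (adjusted p = 0.539 and 0.344), and with 75th percentile scaling 0 and 1 did (adjusted p = 0.225 and 0.193). In A. thaliana the mean was -0.44 (adjusted p = 0.0846), though the same 3 probes fell as in A. arenosa, and in F7 it was -0.50 (adjusted p = 0.197) and 0 fell. The p-values are from camera with Benjamini-Hochberg adjustment over 10 lists.

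No comparison passed camera for the remaining lists with the array files' labels. The lowest adjusted p-values were 0.0617 for lineage-restricted microRNAs such as miR158a, miR161 and miR163, 0.102 for the 51 probes of ancient families, 0.0846 for leaf and organ development (miR164, miR165, miR166, miR319), and 0.0846 for floral organ identity. They were 0.244 for the auxin pathway (miR160, miR167, miR393), 0.264 for small RNA pathway feedback (miR162, miR168, miR403), and 0.496 for the trans-acting siRNA triggers miR161, miR173 and miR390. By the value table's labels floral organ identity passed in F7 leaves above the progenitor mean (mean 0.18, adjusted p = 0.0143, and adjusted p = 0.173 with an estimated correlation), where miR172a and miR172e rose, and in A. thaliana buds against leaf (adjusted p = 0.0475, and adjusted p = 0.150 with an estimated correlation).

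Under the same labels the lineage list passed in A. suecica buds against leaf (mean 0.21, camera adjusted p = 0.0277, and adjusted p = 0.0262 with an estimated correlation), where miR173 rose. In A. suecica against F7 leaves the auxin pathway (mean 0.30, adjusted p = 0.0285) and the triggers (mean 0.41, adjusted p = 0.0337) passed, and neither did with an estimated correlation (adjusted p = 0.0682 and adjusted p = 0.0740). The nutrient list passed in A. arenosa buds against leaf (adjusted p = 0.0256, and adjusted p = 0.0169 with an estimated correlation), where 4 miR169 probes rose. Without leaf arrays 4 to 6 floral organ identity passed above the progenitor mean in F7 leaves (adjusted p = 0.00202, and adjusted p = 0.00753 with an estimated correlation) and in A. suecica leaves (adjusted p = 0.0105, and adjusted p = 0.0300 with an estimated correlation). These p-values are from camera with Benjamini-Hochberg adjustment.

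The F-box list had 2 probes, too few to test, and neither miR393a nor miR394a passed alone in any comparison (lowest adjusted p by limma with Benjamini-Hochberg 0.583 and 0.303).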

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

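The search for single arrays far from their group was set before the data were examined. In 84 groups of leaf arrays of named probes, 4 had an array that stood apart. The threshold assumes 9 independent arrays, while these came in sets of 3, so the number that chance alone would give is not known. The gap to its neighbour as a share of the range was 0.504 for miR171a in A. arenosa (array 4 at 7.32, nearest 7.71) and 0.674 for miR171a in A. suecica (array 7 at 7.34, nearest 8.03). It was 0.495 for miR157d in A. arenosa (array 2 at 7.82, nearest 8.75) and 0.633 for ta-siR752 in A. arenosa (array 7 at 6.07, nearest 6.62). No array was removed.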

How the results depend on the processing

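Alternatives listed before the data were examined come first. Those that left out leaf arrays by set, used the spot mean, a fixed set block or the background of other organisms' probes, and the lists' results under 75th percentile scaling and no normalization, were chosen after seeing the data. Counts of called probes from limma with Benjamini-Hochberg adjustment are given in a fixed order. In leaf and in flower the order is A. arenosa against A. thaliana, F7 against the progenitor mean, A. suecica against that mean, A. suecica against F7. For flower against leaf it is A. thaliana, A. arenosa, F7, A. suecica. The reported counts were 0, 0, 0 and 0 in leaf, the same in flower, and 7, 8, 4 and 8 for flower against leaf. Differences in tissue effect numbered 0, comparisons with single progenitors 3 and list results 8.

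The treatment of the sets moved the counts. With no random block the counts were 10, 4, 3 and 0 in leaf, 9, 0, 6 and 0 in flower, and 25, 30, 24 and 36 between tissues, with 6 differences in tissue effect and 23 against single progenitors. With sets by the remainder of the array number they were 25, 8, 8 and 0, then 10, 3, 8 and 2, then 33, 42, 34 and 42. With each flower array its own set they were 1, 0, 1 and 0, then 7, 0, 6 and 1, then 12, 24, 19 and 27. With set means as samples, where the lone flower mean is assumed to vary like the leaf means, no species comparison had a call, and the tissue counts were 0, 2, 2 and 3. Set medians gave 0, 1, 2 and 3.

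With the array number as a replicate block in place of the sets, the counts were 16, 10, 10 and 0 in leaf, 8, 0, 11 and 1 in flower, and 32, 38, 30 and 40 between tissues, with 46 against single progenitors and 13 differences in tissue effect. In leaf the pairs of arrays with equal numbers had residual correlations from -0.280 to 0.648, median 0.305, and 45 of 54 were above 0.1. The number was nevertheless not taken as a pairing there, and this block counts the arrays of a set as separate samples. With only the arrays of the tissue or species concerned the leaf counts stayed at 0, flower, which then has no block, gave 18, 12, 21 and 15, and the tissue counts were 1, 10, 11 and 8.

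Normalization changed the tissue results. Median scaling left 0, 1, 0 and 0, with 0 against single progenitors and 14 list results, and 75th percentile scaling and no normalization left 0 in each. Under 75th percentile scaling the median difference over all probes shifted to -0.84, -0.90, -0.38 and -0.55 between tissues, and without normalization to 0.46, 0.13, 0.13 and 0.034. With median scaling it was 0.24, 0.14, -0.0045 and -0.064. The sign of miR156h in A. thaliana reversed, from -1.03 to 0.095 with median scaling (limma, Benjamini-Hochberg adjusted p = 0.951) and to 0.31 without normalization (adjusted p = 0.996). Without background correction 1 probe passed in A. suecica leaf against the progenitor mean, and the tissue counts did not move.

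With no filter on dim probes the counts were 1, 0, 1 and 0 in leaf, 0, 0, 1 and 0 in flower and 8, 16, 12 and 9 between tissues, with 7 against single progenitors. Probes bright in every group of the contrast left 0, 2, 1 and 1 between tissues. With other organisms' probes included the counts were 1, 0, 1 and 0, then 0, 0, 2 and 0, then 11, 29, 13 and 13. At least 2-fold left 5, 7, 4 and 8.

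With the deposited value table the counts were 10, 3, 5 and 1 in leaf, 1, 0, 1 and 0 in flower and 13, 16, 9 and 12 between tissues, with 1 difference in tissue effect, 29 against single progenitors and 15 list results. Leaving out leaf arrays 4 to 6 gave 8, 2, 4 and 1, then 1, 0, 1 and 0, then 14, 19, 8 and 12, with 1 difference in tissue effect, 26 against single progenitors and 12 list results. Leaving out leaf arrays 1 to 3 gave 0, 8, 1 and 3 between tissues. Leaving out leaf arrays 7 to 9 gave 2 for A. suecica leaf and 5 for A. suecica flower against the progenitor mean, and 3, 16, 12 and 15 between tissues.

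A fixed block for the hybridization set beside the random one gave 4, 0, 1 and 0 in leaf. Together with the value table it gave 28, 9, 13 and 12. The value table alone turned the signs of miR398b in A. arenosa against A. thaliana (to -0.67, limma with Benjamini-Hochberg adjusted p = 0.260) and of miR163 in A. suecica against F7 (to -0.82, adjusted p = 0.262). With the fixed block added they passed at the same size (adjusted p = 0.0120 and adjusted p = 0.0113). The spot mean in place of the spot median gave 7, 7, 3 and 6 between tissues. Testing only probes above other organisms' probes gave 0, 6, 1 and 4.

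Leaving out each array number in turn gave 0 to 1 calls in leaf for A. arenosa against A. thaliana and for A. suecica against the progenitor mean, and 0 throughout for the other species comparisons. Between tissues the ranges were 0 to 8, 8 to 9, 1 to 4 and 5 to 9. Comparisons with single progenitors gave 1 to 4. In A. thaliana 0 probes passed without number 3 or 8.

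For lists, camera with an estimated correlation gave 4 results in place of 8, fry 9, and families collapsed to 1 value 6. No result was obtained with a linear progenitor mean. With the files' labels no probe was called against the log2 mean, and the value table's calls against it were not checked on the linear scale. Over the named probes and planned settings, 2794 values kept direction and verdict, 192 kept direction and lost the call, 263 kept direction and gained it, and 94 changed sign.

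Signs also turned in values that had passed neither way. There were 128 sign changes in 39 of 148 named results, and only the 4 values given above had passed in the reported fit or in the alternative. The rest follow as log2 differences.

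Under median scaling, the sign turned in miR168a (0.095) for F7 against the progenitor mean in leaf, and miR403 (0.0011) for A. suecica against the progenitor mean in leaf. miR156a (-0.018) for A. suecica against F7 in leaf, and miR172a (-0.25), miR156a (-0.46) and miR403 (-0.0081) for F7 against the progenitor mean in flower turned too. miR156a (-0.22), miR403 (-0.027) and ta-siR255 (-0.0083) for A. suecica against the progenitor mean in flower, and miR168a (0.011) and miR403 (-0.019) for A. suecica against F7 in flower turned too. miR168a (0.78), miR156a (0.66) and miR403 (0.086) for flower against leaf in A. thaliana, and miR163 (0.63), miR168a (0.29), miR172a (0.50) and miR156a (0.34) for flower against leaf in A. arenosa turned too. miR172a (0.013) and miR156a (0.18) for flower against leaf in F7, and miR168a (0.058) and miR156a (0.44) for flower against leaf in A. suecica turned too.

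Without normalization, the sign turned in miR403 (-0.0020) for F7 against the progenitor mean in leaf, and miR172a (-0.33), miR156a (-0.54) and miR403 (-0.087) for F7 against the progenitor mean in flower. miR156a (-0.26), miR403 (-0.071) and ta-siR255 (-0.052) for A. suecica against the progenitor mean in flower, and miR168a (0.046) for A. suecica against F7 in flower turned too. miR168a (0.997), miR156a (0.88) and miR403 (0.30) for flower against leaf in A. thaliana, and miR163 (0.62), miR168a (0.28), miR172a (0.49) and miR156a (0.34) for flower against leaf in A. arenosa turned too. miR172a (0.15) and miR156a (0.31) for flower against leaf in F7, and miR168a (0.16) and miR156a (0.54) for flower against leaf in A. suecica turned too. Under 75th percentile scaling, the sign turned in miR403 (-0.029) for F7 against the progenitor mean in leaf, and ta-siR255 (0.39) for F7 against the progenitor mean in flower. miR398b (0.47) for A. suecica against the progenitor mean in flower, and miR403 (-0.089) for A. suecica against F7 in flower turned too. miR163 (-0.056) for flower against leaf in F7 turned too.

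The value table turned miR168a (0.067), miR156a (-0.054) and miR398b (-0.67) for A. arenosa against A. thaliana in leaf, and miR168a (0.038), miR398b (-0.017), miR403 (-0.16) and ta-siR255 (-0.16) for F7 against the progenitor mean in leaf. miR163 (-0.15) and miR403 (0.19) for A. suecica against the progenitor mean in leaf, and miR163 (-0.82), miR156a (-0.14) and miR403 (0.35) for A. suecica against F7 in leaf turned too. miR163 (1.02) for flower against leaf in A. arenosa, and miR163 (-0.33) for flower against leaf in F7 turned too. miR156a (0.042) for flower against leaf in A. suecica turned too. The fixed set block left the value table's leaf values as they were.

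Leaving out leaf arrays 4 to 6 turned miR172a (-0.013) and miR398b (-0.19) for A. arenosa against A. thaliana in leaf, and miR398b (-0.18) and miR403 (-0.25) for F7 against the progenitor mean in leaf. miR163 (-0.23) for A. suecica against the progenitor mean in leaf, and miR163 (-0.76), miR156a (-0.14) and miR403 (0.19) for A. suecica against F7 in leaf turned too. miR163 (1.13) for flower against leaf in A. arenosa, and miR163 (-0.014) for flower against leaf in F7 turned too. miR163 (0.11) and miR156a (0.22) for flower against leaf in A. suecica turned too. Leaving out leaf arrays 1 to 3 turned miR160a (-0.10) for A. suecica against the progenitor mean in leaf, and miR168a (0.019) and miR172a (-0.17) for A. arenosa against A. thaliana in leaf. miR398b (-0.12) for F7 against the progenitor mean in leaf, and ta-siR255 (-0.0056) for A. suecica against the progenitor mean in flower turned too. Leaving out leaf arrays 7 to 9 turned miR156a (-0.032) for A. arenosa against A. thaliana in leaf, and miR403 (0.042) for A. suecica against the progenitor mean in leaf. miR403 (0.061) for flower against leaf in A. thaliana, and miR163 (-0.20) for flower against leaf in F7 turned too.

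Set medians turned miR156a (-0.021) for A. arenosa against A. thaliana in leaf, and miR403 (0.028) for A. suecica against the progenitor mean in leaf. ta-siR255 (-0.066) for A. suecica against the progenitor mean in flower, and miR168a (0.043) and miR403 (-0.059) for A. suecica against F7 in flower turned too. miR163 (0.060) for flower against leaf in A. arenosa, and miR163 (-0.035) for flower against leaf in F7 turned too. The spot mean turned miR403 (0.0011) for A. suecica against the progenitor mean in leaf. No background correction turned ta-siR255 (-0.0047) for A. suecica against the progenitor mean in flower. The replicate block turned miR168a (0.11), miR172a (-0.14) and miR403 (0.037) for flower against leaf in A. thaliana, and miR163 (-0.13) for flower against leaf in F7. miR168a (0.14) for flower against leaf in A. suecica turned too. Leaving out 1 array number at a time, the values spanned 0 in miR403 (-0.053 to 0.049) for A. suecica against the progenitor mean in leaf, miR156a (-0.0050 to 0.11) for A. suecica against F7 in leaf, miR403 (-0.089 to 0.18) for F7 against the progenitor mean in flower, miR398b (-0.098 to 0.028), miR403 (-0.076 to 0.19) and ta-siR255 (-0.050 to 0.028) for A. suecica against the progenitor mean in flower, miR168a (-0.046 to 0.022) for A. suecica against F7 in flower. The same was so in miR172a (-0.018 to 0.32) for flower against leaf in A. thaliana, miR163 (-0.16 to 0.081) for flower against leaf in A. arenosa and miR163 (-0.096 to 0.14) for flower against leaf in F7.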

Other observations

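The 2 tests on the species of leaf arrays 4 to 6, the test of normalization for miR163 and the exchanges of species within leaf sets were chosen after the result was seen. The other tests had their predicted outcomes written down beforehand.

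By their correlations, leaf arrays 4 to 6 are likely to carry another species' label in the files, though the positions of the species in the files go the other way. Of the 24 ways to give these 4 hybridizations to the 4 species, only 1, the value table's own, had a mean correlation as high with the same species' other leaf sets (0.518, standard error 0.067, next best 0.280). Sets 1 and 3 correlated with each other at 0.444. With miR163 left out the value table's way gave 0.444 and was again the best of 24. With the files' labels the mean correlation was -0.250 (standard error 0.0856) with 23 of the 24 ways at least as high, and with miR163 left out it was -0.146 (0.0492) with 19. Correct labels predict 0 or above. Without miR163 the files' labels gave -0.183 and -0.560 with sets 1 and 3 in A. thaliana, -0.164 and -0.350 in A. suecica and -0.112 and -0.0225 in F7. The A. arenosa hybridization correlated at 0.126 and 0.0964 with its labelled species. The value table's labels gave values from 0.249 to 0.728 over the 4 species without miR163. The errors cover only the choice of probes, and A. arenosa went the other way, so ordinary spread between hybridizations stays open. A swap of labels at an earlier step, in the plants or in the tubes, was not testable.

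Normalization could not have made the low miR163 of A. arenosa, since the smallest unnormalized difference within leaf sets 1 and 3 and the flower set was -1.80, larger than any shift in array medians. Against this stands a biological difference between the 2 species, for which all sets point 1 way only with the value table's labels. A probe that matches the A. arenosa small RNA poorly might give the same picture. In A. arenosa minus A. thaliana flowers, lineage-restricted probes without miR163 had a median 0.0176 above that of ancient families (standard error 0.11). This median could not show a loss in all members. In flowers of both species miR173*, miR418, miR419, miR771, miR772 and miR779 exceeded the background reference on 0 arrays. The miR447a, miR775 and miR780 probes exceeded it on 3, 3 and 2 A. thaliana and 0 A. arenosa flower arrays. The miR158a, miR161, miR173 and miR404 probes did so on 3 in both, miR158b on 3 and 2, and miR415 on 0 and 1. A mismatch at miR163 or at several probes stays open. Sequenced small RNAs of A. arenosa would decide.

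The higher miR171a in flower buds could still come in part from normalization or from the hybridization rather than the tissue. Under 3 other scalings the flower set lay above every leaf set of its species in 11 of 12 cases, the exception being A. thaliana without normalization. With a leaf set taken as the odd one out at most 4 probes passed, in A. arenosa, against 8 for the flower set. The highest counts for a leaf set were 2 in A. thaliana against 7, 0 in F7 against 4 and 3 in A. suecica against 8. The 3 bud arrays of a species were taken as 1 hybridization, and a second, independent one would decide. The poplar probe miR171c, when all probes were tested, rose in buds by 1.61 in A. thaliana, 3.03 in A. arenosa, 2.25 in F7 and 2.68 in A. suecica. The maize probe miR171a rose by 1.14, 2.37, 1.96 and 1.74. Not all miR171 probes rose. The maize probes miR171b, miR171c and miR171f had mean log2 levels of 8.58, 8.45 and 8.60 in leaf and 8.58, 8.39 and 8.49 in flower. All these probes share the hybridizations of miR171a, so they do not separate tissue from hybridization.

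The leaf counts were set against those after regrouping the hybridizations, the real grouping counted in. No biological explanation was tested for them. With the value table's labels as many probes passed in 1 of 10, 25 of 100, 23 of 100 and 3 of 10 groupings, for A. arenosa against A. thaliana (10 probes), F7 (3) and A. suecica (5) against the progenitor mean, and A. suecica against F7 (1), with highest other counts of 8, 16, 21 and 9. The 10 groupings of 2 species are too few for a share under 0.05. With the files' labels the real groupings had 0 calls, which leaves nothing to test, while other groupings gave up to 6, 14, 11 and 11 calls. With the value table's labels some other groupings gave more calls than the real one, except for A. arenosa against A. thaliana. These groupings move hybridizations between sets of unlike intensity and move progenitor differences into the comparison with the progenitor mean. They are therefore no clean reference for chance.

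Each leaf set held all 4 species, so the species were also exchanged within sets only, with the set as a fixed block. With the value table's labels F7 had 9 calls against the progenitor mean, and 17 of 100 exchanges gave as many (highest other 27). A. suecica had 13, and 10 of 100 did (highest other 26). The counts against the progenitor mean were therefore not set apart from chance groupings in either design, although an exchange also moves real differences between the progenitors into the comparison. For A. arenosa against A. thaliana the count was 28, against at most 4 in the others, and for A. suecica against F7 it was 12 against 0, in each case the highest of 4 ways, 1 of 4 reaching the real count, which is too few for a share under 0.05. With the files' labels A. arenosa against A. thaliana had 4 calls, reached in 2 of 4 ways (highest other 7), and A. suecica against the progenitor mean had 1, reached in 63 of 100 (highest other 19).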
